A study of Mus musculus with 8 samples.

How the data were processed

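Gene expression was measured in macrophages sorted by flow cytometry from mouse pancreas tumours, with 1 array per sample. The labels placed 4 samples in an MHCII-high group and 4 in an MHCII-low group, after the amount of MHC class II, the surface complex that presents peptides to CD4 T cells. Per the labels, tumours had been implanted in female mice of a strain given as FvBn, cells were sorted straight into a lysis solution, total RNA was amplified with the Sigma WTA2 kit and the product was labelled chemically with Cy5. Gates other than MHCII were not given in the sources used here. The series' design text names macrophages of normal pancreas or tumours of wild-type, KPC or FLT3-CRE/LSL-YFP mice, and the labels, which give no genotype, do not say which of these the 8 samples belong to. Each group holds the label numbers 20435, 20436, 20439 and 20442 once, and the labels do not say what these numbers mark. Nothing in the labels says that the 4 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

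The deposited scanner files hold the intensity of each spot in 1 colour, on a linear scale, from Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. The processed signal had been background-subtracted and detrended within each array, with surrogate values for dim spots and without dye normalization, per the file headers. All 8 arrays lay on 1 slide with 1 scan time, in 2 rows of 4, per the file headers. Row 1 held 1 MHCII-high and 3 MHCII-low arrays, and row 2 held 3 MHCII-high and 1 MHCII-low arrays. The deposited series table holds log2 values per probe, and no source used here states how the authors made it. In that table the array medians lay between 9.38137 and 9.38149. Each column correlated with the log2 processed signal of its own array at r of 0.998 to 0.9998 across probes, which are not independent replicates, and at 0.999996 or higher with a quantile normalization of those signals computed here. Its scale and direction were therefore those of the log2 processed signal, with no centring of genes.

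Each array had 62976 spots, of which 3671 controls were left out, and 59305 spots of 56605 probes remained. Spots marked as outliers by the scanner software, 67 to 160 per array, were left out, and no spot was saturated. Log2 processed signals were expressed relative to the 75th percentile of their array, and spots of the same probe were averaged. Probes well above background on at least 4 of the 8 arrays were kept, and a gene was represented by its brightest probe over all arrays. This left 27963 genes. The depth of an array was read from its probes well above background, 38756 to 42120 per array (68.5% to 74.4%), and the number of arrays limits the precision. Gene names came from the RefSeq table of assembly GRCm38.p6, used for names only. The main identifier of the probe matched for 32994 probes, another identifier for 895 and an older symbol for 489, while 22227 kept the name in the files. Of the genes tested, 19614 had a RefSeq symbol. Probe coordinates are those of the files, on mm9. No exon or UTR annotation of that build was used here.

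Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. Tests were two-sided. Fold changes are MHCII-high against MHCII-low, and 95% intervals of single genes come from the moderated standard error. Intervals of per-array list means hold the shifts that an exact permutation over the 70 assignments of 8 arrays did not reject at 0.05. These assignments treat the 8 arrays as interchangeable. That would not hold if the label numbers mark pairs, and the permutation p-values would then be too small. For a gene not well above background on any array of a group, the fold is a lower bound against the higher of the array's lowest signal well above background and the probe's own signal. Medians of the 30 lists were the same to 2 decimals with such genes at their bound. Among the top genes, values against dim signals have no meaningful order. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with camera at an estimated correlation and fry beside it. The comparison, the lists, the rule for named genes and the alternatives listed here, except where said, were set before the data were examined. The 30 lists cover 614 genes, of which 39 are in more than 1 list. They hold antigen presentation (MHC class I and II pathways), T cell costimulation and checkpoint ligands, chemokines attracting T cells or myeloid cells, inflammatory mediators, type I interferon and interferon gamma responses, alternative activation, tissue-resident macrophage, pan-macrophage and monocyte genes, hypoxia and glycolysis, lipid handling and lysosome, complement and scavenging, matrix remodelling, growth and angiogenic factors, cell cycle, immediate early and heat shock, ribosomal protein and mitochondrial respiration genes. Markers of cells that a gate could let through were listed too: dendritic cells, neutrophils, T and NK cells, B and plasma cells, mast cells with basophils and eosinophils, fibroblasts and pericytes, endothelium, tumour epithelium and duct, and acinar and islet cells.

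Named genes were the 12 with the largest log2 change in each direction among those past the threshold whose groups did not overlap, skipping names that are only gene models or clones, up to 4 members of each list with the smallest unadjusted p, and all measured MHC class II pathway genes. This gave 143 genes. A few genes are not reported here by name but stay in the counts and lists, and 1 of them was taken out of the set of macrophage genes chosen after values were seen, once the result of the larger set was known. Probes of closely related genes (the Klr, Cd209, H2, Chil, Lyz and H2al1 families) may bind each other's transcripts, so these genes are uncertain. Of 537 genes past the threshold with more than 1 probe, 88 had a probe of the opposite sign, and 8 of these at an unadjusted p under 0.05.

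The fit and the list test were checked on data simulated for MHCII-high against MHCII-low over 27963 genes. Genes changed by log2 0.5, 1 and 2 were recovered in 0%, 14.9% and 77.3% of cases, with 1 false call among 62. Only 67, 67 and 66 genes were changed, far fewer than the 1382 called in the data. The Benjamini-Hochberg method was then stricter on the unadjusted p, so these recovery rates do not carry over to the data. With no change simulated, 0 genes and 0 lists were called, and a list given a shift was the only list called. The simulated genes varied independently of each other, so this did not check the list test on genes that vary together. The correlation estimated from the data was 0.36 for the dendritic cell list and 0.49 for the tissue-resident macrophage list. Alternatives were the label number or the slide row as a block, quantile normalization, normexp background correction (offset 50) of the mean signal, no filter on dim probes or a filter on all 8 arrays, the mean over the probes of a gene, the series table, and each array left out in turn. A fit without either array numbered 20442 was added after seeing the data. Files were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.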

Results

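The series profiled macrophages of pancreas tumours, the phagocytes that clear debris and can present antigen, as 4 MHCII-high and 4 MHCII-low samples on 1-colour arrays. Between 38756 and 42120 of 56605 probes were well above background per array. Correlations between arrays across genes, which are not independent replicates, were 0.951 to 0.968 within MHCII-low, 0.950 to 0.971 within MHCII-high and 0.908 to 0.961 between the groups. Component 1 of a principal component analysis held 37.5% of the variance and placed MHCII-low arrays at -72.1 to -45.0 and MHCII-high arrays at 30.0 to 101. Component 2 held 16.7%.

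The labels set MHCII-high against MHCII-low macrophages, which asks how the transcripts of these populations differ. Dendritic cell genes (16 of 24 past the threshold) and 3 of 11 T cell-attracting chemokines, Ccl17, Ccl22 and Cxcl9, were higher in MHCII-high cells, and tissue-resident macrophage (14 of 23), complement and scavenging (9 of 28) and lipid handling and lysosome genes (8 of 30) were higher in MHCII-low cells. These lists passed limma's camera at a preset correlation, while 0 of 30 lists passed with an estimated correlation. The dendritic cell list had a median log2 fold change of 2.05 and the tissue-resident macrophage list one of -1.30. Of 27963 genes tested with limma, 1382 (4.94%) passed an adjusted p of 0.05, with 751 higher in MHCII-high and 631 higher in MHCII-low. At least 2-fold changes made up 989 of them, 561 toward MHCII-high and 428 toward MHCII-low. The groups did not overlap for 4043 genes (14.5%), where chance gives 2.86%, and for 1377 of the 1382. Among the genes past the threshold, 43 were not well above background in any MHCII-low array and 17 in any MHCII-high array, and 354 had names of gene models or clones. With the slide row as a block 455 genes passed, 300 toward MHCII-high and 155 toward MHCII-low, 432 of them among the 1382, while the median size of the 1382 log2 changes went from 1.32 to 1.28 and the median standard error from 0.22 to 0.26. Of 85 named genes past the threshold, 41 kept the call with that block and 64 with the label number as a block. Each row holds 1 array of one group and 3 of the other, so values within a row rest on a single array of a group and are given for direction only. Median sizes of the 1382 changes within rows 1 and 2 were 1.12 and 1.44. The count was 724, 864, 822 and 833 without MHCII-low 20435, 20436, 20439 and 20442, and 555 and 781 without MHCII-high 20439 and 20442.

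The sort itself was read from the MHC class II pathway, which checks the labels and is not a finding. Of 16 measured members, 10 were higher in MHCII-high and 0 lower, and 11 and 0 when adjusted over the list alone. Ciita, the master regulator of class II transcription, was 8.15-fold higher (95% interval 5.56 to 11.9, adjusted p = 0.000877), with a mean log2 signal of 3.14 ± 0.25 (SD, n = 4) against 0.11 ± 0.44 (SD, n = 4). Its probe lies on chromosome 16 of mm9 at 10526458 to 10526517. H2-Ab1, a class II beta chain with its probe on chromosome 17 at 34406296 to 34406355, was 3.99-fold higher (2.96 to 5.39, adjusted p = 0.00183). H2-DMb2 and H2-Oa rose by log2 3.34 each, H2-Ob by 2.71, H2-Eb1 by 2.01, H2-DMa by 1.60, H2-Aa by 1.07, H2-DMb1 by 0.95 and Cd74, the invariant chain, by 0.89. A further H2-Ob probe gave -0.48. Values not past the threshold were 1.45 for H2-Eb2, 0.88 for Rfx5, 0.08 for Ifi30, 0.05 for Rfxap, -0.10 for Ctss and -0.20 for Rfxank. A second H2-Eb2 probe gave 3.21. The list median was 1.26 (camera adjusted p = 2.76e-11), 1.21 with the slide row as a block, and 1.04 and 1.22 within rows 1 and 2, with an adjusted p = 0.118 with an estimated correlation. Cd74 lost its call in 6 of the 8 fits with 1 array left out (adjusted p up to 0.0778), H2-DMb1 without MHCII-low 20435 (0.0585) or MHCII-high 20439 (0.0578) and H2-Aa without MHCII-low 20435 (0.0507). All 3 lost it with the slide row as a block (0.110, 0.0724 and 0.0751 in this order).

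The genes with the largest increases in MHCII-high included Flt3, a receptor that drives dendritic cell development, and several members of the killer cell lectin-like receptor family. Of 20 T and NK cell genes, however, Klrd1 alone passed, and the list median was -0.17 (camera adjusted p = 0.83). Among the others, Ncr1 was at 0.26 and Klrb1c at 0.45. The Klr genes are thus not read as a sign of natural killer cells. Flt3 was 22.1-fold higher (11.1 to 44.1, adjusted p = 0.00215), and its probe lies on chromosome 5 at 148142576 to 148142635. A second Flt3 probe gave 0.25. Adgrg5, an adhesion G protein-coupled receptor, was 23.6-fold higher (14.4 to 38.5, adjusted p = 0.000456). Both genes were well above background on all 8 arrays. Gcsam had a log2 change of 6.16 (adjusted p = 0.0114), 3.31 with normexp background correction, and was well above background on 1 of 4 MHCII-low arrays, like F2rl2 (5.18, 2.22 with normexp), Klrb1 (5.12, 2.68), Gpr141b (4.51, 2.02) and Apol7c (4.48, 1.58). Klri1 (5.73, 3.34) was above background on 2 and Klrd1 (4.84, 2.95) on 3 of the 4. A second Klrb1 probe gave -0.07. For Fndc5, Mfsd2a and Afm, not well above background on any MHCII-low array, the increase was at least 7.91-fold (adjusted p = 0.00119), at least 9.64-fold (adjusted p = 0.000833) and at least 5.28-fold (adjusted p = 0.00018) in the processed signal, but the log2 change with normexp was lower than these bounds, at 2.65, 2.12 and 1.59. With the slide row as a block the log2 change was 4.20 for Flt3 (4.41 and 3.99 within the rows) and 5.96 for Gcsam (6.61 and 5.31), whose adjusted p became 0.056. Klrd1 lost its call in 5 of 8 fits with 1 array left out (adjusted p up to 0.0685) and Gpr141b in 6 (up to 0.0971), and both lost it with the row block (0.0948 and 0.0807).

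Dendritic cell genes were raised together in MHCII-high. Of 24 measured, 16 were higher and 0 lower, and 20 and 1 when adjusted over the list alone (camera adjusted p = 2.61e-17, adjusted p = 0.23 with an estimated correlation). Besides Flt3, the peptidase Dpp4 rose by log2 3.40 (10.5-fold, 7.05 to 15.7, adjusted p = 0.00061), the lectin Cd209a by 3.06 (8.32-fold, 5.47 to 12.7) and Batf3, a transcription factor of conventional dendritic cells, by 1.75 (3.36-fold, 2.59 to 4.36). A second Dpp4 probe gave 0.0036. The list median of 2.05 was 1.97 with the slide row as a block, and 2.0 and 2.51 within rows 1 and 2. The per-array mean of the macrophage genes Mertk, Fcgr1 and Cd14, a set chosen after values were seen and changed after a first result, differed by -0.29 (MHCII-high minus MHCII-low, exact permutation p = 0.0857), and by -0.64 (p = 0.0286) together with Adgre1, itself past the threshold. Leaving Adgre1 out because it passed moves the mean toward no difference.

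**Figure D1:**
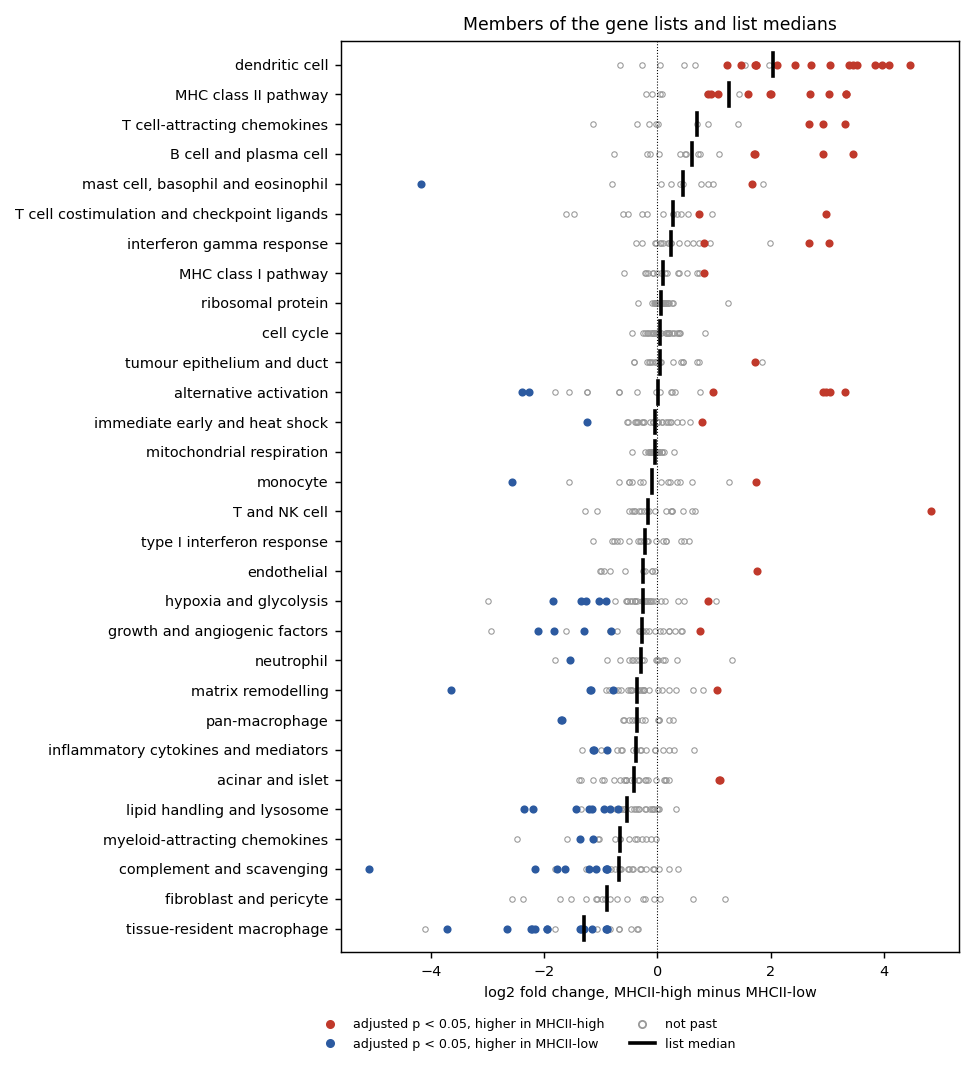
Log2 fold change (MHCII-high minus MHCII-low, horizontal axis) of each measured member of the 30 gene lists (vertical axis), from 4 arrays per group. Filled points passed an adjusted p of 0.05 (red higher in MHCII-high, blue higher in MHCII-low), open points did not, and black bars mark list medians, from 2.05 for the dendritic cell list to -1.30 for the tissue-resident macrophage list.

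Chemokines that attract T cells were higher in MHCII-high for 3 of 11 measured genes and lower for 0, and for 6 and 1 when adjusted over the list alone. Ccl17, which draws CCR4-bearing T cells, rose by log2 2.93 (7.62-fold, 4.89 to 11.9, adjusted p = 0.00189), and Cxcl9, an interferon gamma-induced chemokine, by 2.68 (6.39-fold, 3.84 to 10.6). Ccl22 was not well above background in MHCII-low and was at least 2.50-fold higher in the processed signal (adjusted p = 0.000499), but by log2 0.85 with normexp (adjusted p = 0.0164). Mature dendritic cells also make Ccl17 and Ccl22, and the dendritic cell list had a median of 2.05 in the same comparison. Ccl8 had a log2 change of -1.15 and did not pass (adjusted p = 0.0585). The list median was 0.70 (camera adjusted p = 0.00419), 0.53 with the slide row as a block, 0.61 and 0.44 within the rows and 0.36 with no filter on dim probes or a filter on all 8 arrays, with an adjusted p = 0.262 with an estimated correlation.

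Interferon gamma response genes were higher in MHCII-high for 3 of 20 and lower for 0, and for 7 and 0 when adjusted over the list alone (median 0.23, camera adjusted p = 0.000298, adjusted p = 0.23 with an estimated correlation). The 3 were Ciita, Cxcl9 and Psmb9, an immunoproteasome subunit, at 0.81, all held by other lists too. Ciita is also in the MHC class II pathway list, whose rise the sort fixes. Gbp2, of the interferon gamma list, was at 0.62 (adjusted p = 0.0535). The list median was 0.16 with the slide row as a block and 0.27 and 0.15 within the rows. The MHC class I pathway had Psmb9 as its 1 member past the threshold of 16 and 4 higher and 1 lower when adjusted over the list alone (median 0.10, camera adjusted p = 0.162). In that list Tap1 was at 0.73, Psmb8 at 0.69 and Canx at -0.59, none past the threshold. Costimulation and checkpoint ligands had 2 of 15 higher, Pdcd1lg2 (PD-L2) at 2.99 (7.94-fold, adjusted p = 0.00123) and Cd80 at 0.74, with 4 higher and 4 lower when adjusted over the list alone (median 0.28, camera adjusted p = 0.324, fry adjusted p = 0.0132 upward). Dendritic cells can express Pdcd1lg2 and Cd80 too, and the dendritic cell list had a median of 2.05 in the same comparison. Icosl was at 0.96 and Il18 at -1.62, not past the threshold. A second Icosl probe gave 1.31. Psmb9 lost its call in 5 of the 8 fits with 1 array left out (adjusted p up to 0.0763) and Cd80 in 6 (up to 0.0746), and both lost it with the slide row as a block (0.101 and 0.102).

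The genes with the largest increases in MHCII-low included Slc40a1, the iron exporter ferroportin, and Cd209b, a C-type lectin of macrophages. Slc40a1 was 34.3-fold higher in MHCII-low (6.58 to 179, adjusted p = 0.0311) by its brightest probe, on chromosome 1 at 45965255 to 45965314, while a second probe gave -0.88. It was well above background on 3 of 4 MHCII-high arrays. Cd209b, Kcna2 and H2al1h were not well above background on any MHCII-high array and were at least 8.47-fold (adjusted p = 0.00233), 5.74-fold (adjusted p = 0.0083) and 4.85-fold (adjusted p = 0.0083) higher in MHCII-low in the processed signal, with smaller log2 changes of -1.75, -1.47 and -1.14 with normexp. Ttll11 (log2 -4.85, -1.84 with normexp) and Fgf9 (-4.12, -2.39) were well above background on 1 of 4 MHCII-high arrays, and Serpinb10 (-4.64, -2.46), Fam13a (-4.60, -2.08) and Slc10a6 (-4.49, -2.24) on 2. The eotaxin receptor Ccr3 (-4.19, -2.97), Pcolce2 (-4.05, -2.94) and S100b (-4.0, -2.24) were so on 3. With the slide row as a block the Slc40a1 change was -4.61 (adjusted p = 0.123), and -2.52 and -6.70 within rows 1 and 2. In 4 to 7 of the 8 fits with 1 array left out the call was lost for Slc40a1, Serpinb10, Slc10a6, Ccr3, Fgf9, Pcolce2 and S100b, with adjusted p up to 0.121. The same 7 genes and Ttll11 lost it with the row block (up to 0.138).

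Genes of tissue-resident macrophages were lower in MHCII-high for 14 of 23 and higher for 0, and for 20 and 0 when adjusted over the list alone (camera adjusted p = 2.61e-17, adjusted p = 0.23 with an estimated correlation). Cd5l, an inhibitor of apoptosis secreted by macrophages, fell by 3.73 on the log2 scale (adjusted p = 0.00717), Fcna, a ficolin, by 2.66, and Pf4 by 1.37. Timd4, a receptor for phosphatidylserine with its probe on chromosome 11 at 46657173 to 46657232, fell by 2.17 (adjusted p = 0.00594). The list median of -1.30 was -1.41 with the slide row as a block, and -0.80 and -1.57 within rows 1 and 2, and Fcna lost its call with that block (adjusted p = 0.0553). A set of 9 serous-cavity macrophage genes, chosen after values were seen, had a median of -3.12 in the same comparison. Of 15 pan-macrophage genes 2 fell, Adgre1 (F4/80) by 1.69 and the sialoadhesin Siglec1 by 1.71, and 5 did so when adjusted over the list alone (median -0.36, camera adjusted p = 0.000566, adjusted p = 0.357 with an estimated correlation). The Adgre1 probe lies on chromosome 17 at 57550221 to 57550280. Cd68 was at -0.59 and Tlr4 at -0.62, not past the threshold. Other probes gave -1.02 and -0.50 for Cd68, and -1.07 and 0.38 for Tlr4. With the slide row as a block the pan-macrophage median was -0.38, and -0.25 and -0.51 within the rows.

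**Figure D2:**
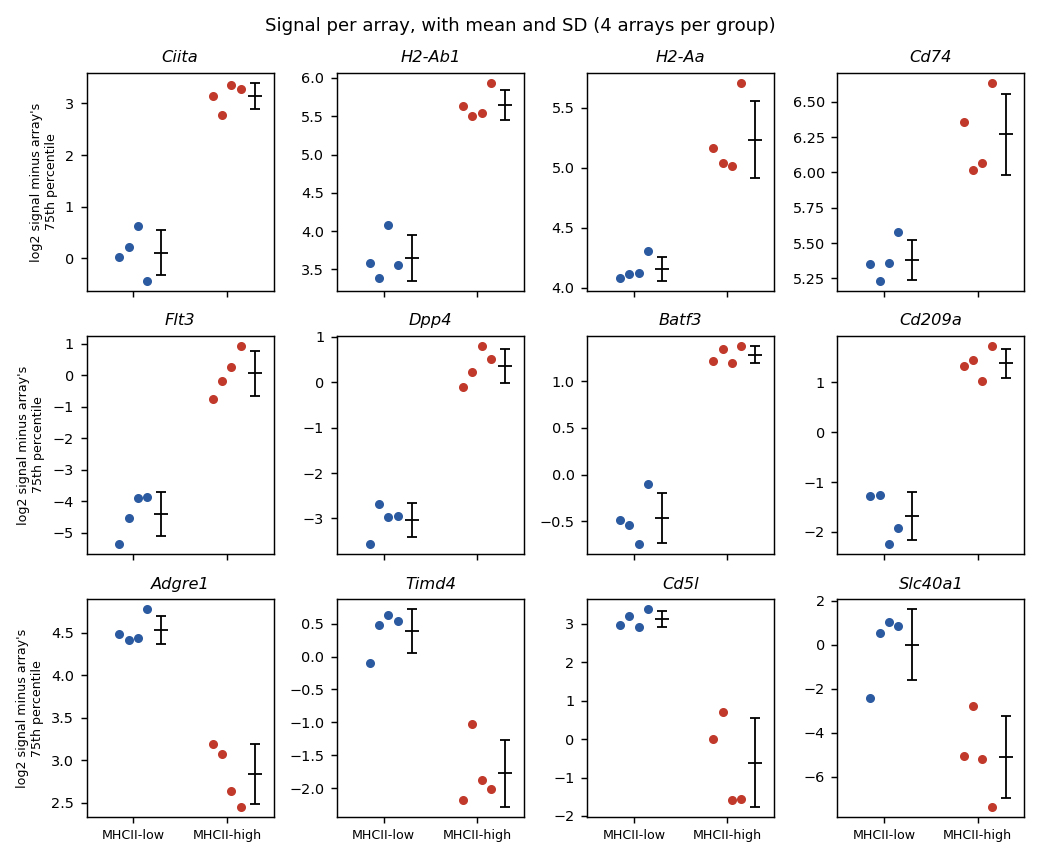
Log2 signal relative to the 75th percentile of the array (vertical axes, scaled per gene) for 12 genes in the 4 MHCII-low (blue) and 4 MHCII-high (red) arrays, with the mean and SD of each group as bars. The groups did not overlap for any of the 12 genes; Ciita averaged 0.11 in MHCII-low and 3.14 in MHCII-high.

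Complement and scavenging genes were lower in MHCII-high for 9 of 28 and for 20 when adjusted over the list alone, and higher for 0 in either case (median -0.67, camera adjusted p = 2.96e-11, adjusted p = 0.262 with an estimated correlation). Besides Timd4, the complement component C4b fell by 1.63 and the scavenger receptor Msr1 by 1.20. The list median was -0.66 with the slide row as a block and -0.44 and -0.96 within the rows. Lipid handling and lysosome genes were lower for 8 of 30 and for 16 when adjusted over the list alone, with 0 higher (median -0.53, camera adjusted p = 1.38e-09, adjusted p = 0.308 with an estimated correlation). The fatty acid carrier Fabp4 fell by 2.20, Gpnmb by 1.44 and Ch25h, which makes 25-hydroxycholesterol, by 1.16. That median was -0.53 with the slide row as a block and -0.44 and -0.67 within the rows. C4b lost its call without MHCII-high 20439 (adjusted p = 0.0515). Calls of C4b, Msr1, Fabp4, Gpnmb and Ch25h ended with the row block (adjusted p of 0.0695, 0.0589, 0.0605, 0.0552 and 0.0604), which left Timd4.

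Myeloid-attracting chemokines fell for 2 of 16 and for 9 when adjusted over the list alone, Pf4 and the monocyte attractant Ccl7 (-1.15) being the 2 (median -0.66, camera adjusted p = 1.03e-06, adjusted p = 0.23 with an estimated correlation). Ppbp was at -1.60 and Csf2 at -2.48, not past the threshold. Csf2 was well above background on 1 of 4 MHCII-high arrays, and passed in limma with the label number as a block (adjusted p = 0.0493). Inflammatory mediators fell for 3 of 20, with 6 lower and 1 higher when adjusted over the list alone (median -0.38, camera adjusted p = 0.000884). The 3 were Nos2, by 1.14, Saa3, by 1.13, and Marco, by 0.90. Marco is a scavenger receptor that is also in the tissue-resident macrophage and the complement and scavenging lists. Inflammatory mediators had an adjusted p = 0.376 with an estimated correlation, and Casp1 was at -0.72 (adjusted p = 0.0581). Matrix remodelling genes fell for 4 of 29 and rose for 1, with 9 lower and 2 higher when adjusted over the list alone (median -0.35, camera adjusted p = 0.000572, adjusted p = 0.262 with an estimated correlation). Serpinb2, also among the serous-cavity genes, fell by 3.65, Thbs1 by 1.17 and Timp2 by 0.79. Growth and angiogenic factors fell for 4 of 24 and rose for 1, with 5 lower and 1 higher when adjusted over the list alone (median -0.27, camera adjusted p = 0.00479, adjusted p = 0.262 with an estimated correlation). Bmp2 fell by 2.11, Gdf15 by 1.83 and Igf1 by 1.30, while placental growth factor Pgf rose by 0.76. Medians with the slide row as a block, within row 1 and within row 2 were -0.63, -0.28 and -0.97 for the chemokines, -0.31, -0.15 and -0.46 for the mediators, -0.40, -0.22 and -0.49 for matrix genes and -0.25, -0.25 and -0.17 for growth factors, whose median was also -0.17 with normexp. Timp2 lost its call in 8 of the 8 fits with 1 array left out, Ccl7, Nos2, Gdf15 and Pgf in 7, Saa3 and Marco in 6 and Igf1 in 4, with adjusted p up to 0.115. Thbs1 lost it without MHCII-high 20439 (0.0567). Of the genes called without a block in this paragraph, Pf4 and Serpinb2 kept the call with the row block, and the others lost it (adjusted p up to 0.133).

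Hypoxia and glycolysis genes fell for 5 of 34 and rose for 1, with 13 lower and 2 higher when adjusted over the list alone (median -0.25, camera adjusted p = 1.49e-05, adjusted p = 0.308 with an estimated correlation). The oxygen-sensing hydroxylase Egln3 fell by 1.84 (adjusted p = 0.00524), P4ha2, a collagen prolyl hydroxylase, by 1.35, Ero1a by 1.26 and Bnip3 by 0.91, while a second P4ha2 probe gave 0.11. The median was -0.34 with the slide row as a block and -0.32 and -0.37 within the rows. Bnip3 and Ero1a lost the call without MHCII-low 20435 or MHCII-high 20439 (adjusted p up to 0.0588 and 0.0552), and also with the row block (0.0779 and 0.0791).

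Alternative activation genes, which interleukin 4 and related signals induce, moved both ways. Of 20, 5 rose and 2 fell, with 6 higher and 7 lower when adjusted over the list alone (median 0.01, camera adjusted p = 0.513). The 5 that rose were Ccl22, Ccl17, Cd209a, Pdcd1lg2 and Mgl2 (log2 0.98). Dendritic cells can express all 5, and the dendritic cell list rose in the same comparison (median 2.05). The 2 that fell were Chil4 (-2.40) and Il10 (-2.28, well above background on 1 of 4 MHCII-high arrays). Mgl2, Chil4 and Il10 were named after their values were seen. The median was -0.018 with normexp background correction and -0.082 with the slide row as a block, while fry called the list upward (adjusted p = 0.019), so its direction depended on the method.

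Some markers of other cell types moved with the groups as well. B cell and plasma cell genes rose for 4 of 14 and for 6 when adjusted over the list alone, and fell for 0 in either case (median 0.62, camera adjusted p = 0.000861, adjusted p = 0.309 with an estimated correlation). Fcrla, well above background on 1 of 4 MHCII-low arrays, rose by 3.45 (1.03 with normexp), the joining chain Jchain by 2.94 and Pou2af1 by 1.71. Of the 14, 11 were above 0, and the 3 below were Bank1 (-0.77), Ms4a1 (-0.19) and Cd22 (-0.13), none past the threshold. These 3 were named after their values were seen. The median was 0.63 with the slide row as a block and 0.97 and 0.14 within the rows. Of 18 fibroblast and pericyte genes limma called 0 (2 at an unadjusted p under 0.05), also when adjusted over the list alone, although camera placed the list lower in MHCII-high (median -0.89, adjusted p = 0.0317, adjusted p = 0.606 with an estimated correlation). That call ended without MHCII-low 20436, 20439 or 20442 (adjusted p = 0.0668, 0.086 and 0.0715) and without MHCII-high 20435 or 20442 (0.257 and 0.0818), the median moving to -0.21 without MHCII-high 20435, and with the slide row as a block (median -0.71, adjusted p = 0.108, -0.22 and -1.29 within the rows). Lum was at -2.57, Pdgfrb at -2.38, Tagln at -0.72 and Mmp2 at 0.64. Jchain lost its call in 7 of the 8 fits with 1 array left out (adjusted p up to 0.0724), and Pou2af1 without MHCII-high 20439 or 20442 (up to 0.0586). Both lost it with the row block (0.0867 and 0.0807).

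The lists of the remaining cell types did not pass. T and NK cell genes had 1 of 20 higher, Klrd1, and 1 when adjusted over the list alone, with a median of -0.17, a mean of 0.11 and a downward camera direction (adjusted p = 0.83). Cd247, Cd3g and Prf1 were at -1.06, -1.28 and 0.61. Other Cd247 probes gave -0.35 and 0.16. Mast cell, basophil and eosinophil genes had 1 higher, Fcer1a (1.67), and 1 lower, Ccr3, of 11, with 1 each when adjusted over the list alone (camera adjusted p = 0.329). Il5ra was at -0.81 and Siglecf at 0.46. Neutrophil genes had 1 of 18 lower, the stefin Stfa3 (-1.55), and 1 when adjusted over the list alone (camera adjusted p = 0.0817), while Ly6g was at 1.32, Stfa2l1 at -1.82 and S100a8 at -0.89. Monocyte genes had Plac8 higher (1.75) and F13a1 lower (-2.58) of 16, with 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.379), and Ccr2 was at 1.27 and Chil3 at -1.57. Of 11 endothelial genes the tight junction gene Cldn5 rose by 1.77, with 1 higher and 1 lower when adjusted over the list alone (median -0.25, camera adjusted p = 0.135), and Eng, Esam and Cdh5 were at -1.02, -0.57 and -0.84. Of 19 tumour epithelium and duct genes Cdh1, E-cadherin, rose by 1.73, with 3 higher and 0 lower when adjusted over the list alone (median 0.04, camera adjusted p = 0.162). Epcam was at 1.84 (adjusted p = 0.0702, and 0.0362 with the label number as a block), Spint1 at 0.74 and Muc4 at 0.46. Other probes gave 1.11 for Spint1, and -0.27 and -0.0066 for Muc4. The per-array mean of 4 keratins, chosen after values were seen, differed by -0.15 (95% interval -1.96 to 1.46). Of 25 acinar and islet genes Zg16 rose by 1.09 and the insulin gene Ins2 2.14-fold, with 2 higher and 1 lower when adjusted over the list alone (median -0.42, camera adjusted p = 0.329), and Cela1 was at -1.36 and Sycn at -0.34. Cdh1 lost its call in 7 of the 8 fits with 1 array left out and Ins2 in 6 (adjusted p up to 0.0979), and Fcer1a without MHCII-low 20439 or MHCII-high 20439 (up to 0.0588). Klrd1, Ccr3, Fcer1a, Cldn5, Cdh1 and Ins2 lost it with the row block (up to 0.138), and Zg16 with the label number as a block (0.0535). Medians changed sign within a row for neutrophil (0.08 in row 1), T and NK cell (0.07 in row 1), endothelial (0.17 in row 2) and acinar and islet genes (0.05 in row 2).

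Limma called 0 of 30 cell cycle genes (median 0.05, camera adjusted p = 0.329), 0 of 32 ribosomal protein genes (0.07, 0.327), 0 of 30 mitochondrial respiration genes (-0.05, 0.329) and 0 of 20 type I interferon genes (-0.22, 0.0816), and 0 in each when adjusted over the list alone (2, 0, 1 and 5 at an unadjusted p under 0.05). Among the named genes of these lists Tk1 was at 0.84, Rpl37 at 1.24, Sdhc at -0.45 and Cmpk2 at -1.15. Other Tk1 probes gave values from -0.27 to 1.65. The type I interferon median was 0.06 within row 1 and the ribosomal one -0.03 within row 2. Immediate early and heat shock genes had Btg2 higher (0.79) and Klf2 lower (-1.25) of 26, with 1 each when adjusted over the list alone (median -0.04, camera adjusted p = 0.501), and these lost their calls in 7 and 4 of the 8 fits with 1 array left out (adjusted p up to 0.0958 and 0.0603) and with the row block (0.120 and 0.0875). A second Btg2 probe gave 0.071.

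In all, 15 of 30 lists passed, 5 toward MHCII-high and 10 toward MHCII-low. The 5 include the MHC class II list, which checks the sort. Each of the 15 kept its direction with the slide row as a block and within each row. With an estimated correlation 0 of 30 passed in limma's camera (5 at an unadjusted p under 0.05), 16 passed with fry and 24 with its test for change in either direction, and 10 of the 35 divisions of the arrays into 4 and 4, the real one included, gave 15 lists or more.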

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

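The tests of dendritic cells inside the gate, of tumour epithelial cells, and of the shift of each list in other splits were chosen only after the results were seen, as were the 9 serous-cavity genes; the counts over other splits and both tests of slide position were set before their results were seen. Each group of 4 arrays was tested for an array far from its nearest neighbour in 364 sets of values, and 19 (5.22%) stood out, where chance gives about 1 in 20.

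Among log2 signals relative to the array's 75th percentile, MHCII-high 20442 was the far array for Psmb8 (4.68, others 4.18 to 4.26), Siglecf (0.17, others 0.93 to 1.06), Zg16 (0.44, others -0.059 to 0.0075), Cela1 (0.75, others 1.85 to 1.94) and Rfxank (-0.92, others -0.49 to -0.44). MHCII-high 20435 was far for Ttll11 (-4.16, others -7.66 to -7.22), Mcm5 (-0.51, others -0.98 to -0.91) and Ctss (5.27, others 5.11 to 5.13). MHCII-high 20436 was far for Mfsd2a (-3.44, others -1.74 to -1.54) and Fgf9 (-4.59, others -7.81 to -7.42). In MHCII-low, 20435 was far for Slc40a1 (-2.41, others 0.51 to 1.03), 20439 for Ccl17 (2.60, others 1.39 to 1.57) and Ifi30 (5.04, others 5.38 to 5.44), 20436 for Rfxank (-0.87, others -0.22 to -0.20) and 20442 for Psmb8 (4.04, others 3.47 to 3.56). The coefficient of variation of replicated spots was 7.42% on MHCII-low 20442 (other MHCII-low arrays 4.13% to 4.39%). It was also high on MHCII-high 20442 (8.40%) and 20439 (6.38%), against 4.00% on MHCII-high 20436 and 4.11% on 20435. As those values spread, no MHCII-high array stood out from its group. The arrays with high values all lay in slide row 2, as did MHCII-high 20435. Per-array means of lists were far for the cell cycle on MHCII-low 20439 (0.30, others 0.061 to 0.084), for fibroblasts and pericytes on MHCII-low 20435 (-0.91, others -0.013 to 0.091) and for inflammatory mediators on MHCII-low 20442 (2.45, others 2.56 to 2.56).

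Other divisions of the 8 arrays into 4 and 4 were compared with the real one, 35 in all. For genes past the threshold 1 split, the real one, gave as many (1382, highest other 5). The same held for genes higher in MHCII-high (751, highest other 5) and in MHCII-low (631, highest other 5). It also held for genes changed at least 2-fold (989, highest other 5). No other division came near these counts, but 1 of 35 is the smallest share possible and the counts share genes. The comparison also treats all 8 arrays as interchangeable, which would not hold if the label numbers mark pairs. The shift of the MHC class II list was as large in 1 split (1.26, highest other 0.76). Sorting on MHC class II fixes that outcome, so it only checks the labels. For the number of lists chance was not excluded: 10 splits gave 15 or more, the highest other gave 18, and the other splits had a median of 11. The split along the slide rows gave 14. Of the 15 lists, 9 had their largest shift in the real split: MHC class II, dendritic cell, tissue-resident macrophage, T cell-attracting and myeloid-attracting chemokines, complement and scavenging, lipid handling and lysosome, matrix remodelling, and growth and angiogenic factors. The margin was small for myeloid-attracting chemokines, with a median of -0.6617 against a size of 0.6603 in another split. For T cell-attracting chemokines it was 0.70 against 0.62 in the split along the slide rows. Of the lists that did not pass, 1 also had its largest shift in the real split.

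Dendritic cell genes were higher in MHCII-high for 16 of 24, with a list median of log2 2.05 (adjusted p = 0.23 with an estimated correlation). Position on the slide is argued against, because 96.1% of the median remained with the slide row as a block. Dendritic cells inside the MHCII-high gate remain open: the per-array mean of Mertk (-0.50), Cd14 (-0.40) and Fcgr1 (0.03) differed by -0.29 (MHCII-high minus MHCII-low, 95% interval -0.76 to 0.13, exact permutation p = 0.0857). Adding Adgre1 (-1.69), already past limma's threshold, gave -0.64 (-1.15 to -0.21, p = 0.0286, the smallest 70 assignments can give), and p = 0.136 in limma's camera with an estimated correlation. Leaving out Adgre1 because it passed moved the mean toward no difference, while keeping it counts a gene already seen to fall. Neither set can therefore decide the question. The set with Adgre1 was changed after a first result was known, and its 4 genes are also in fixed lists. Gates that would remove dendritic cells were not given. A share of dendritic cells in the gate was thus neither shown nor excluded, and a dendritic-like state of the macrophages was not tested.

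A set of 9 genes of serous-cavity macrophages, noticed among the MHCII-low genes, of which 2 are in fixed lists, had a median of log2 -3.12, with 8 of 9 past the threshold (Tgfb2 not, adjusted p = 0.0838). Position on the slide is argued against, since 89.4% of that median remained with the slide row as a block (-2.01 and -3.55 within rows 1 and 2). Serous-cavity macrophages among the MHCII-low cells may contribute: 11 further genes, chosen before their values were seen, had a median of -1.19 (-1.01 with the row block), and 6 of them, Naip1, Padi4, Itga6, Lrg1, Cd93 and Aspa, passed downward. The others did not pass: Fabp7 was at -3.67 (adjusted p = 0.133 in limma), while Rarb (-0.10), Lyz1 (-0.07), Ltbp1 (-0.02) and Garnl3 (0.25) lay near 0 or above. The test of the 11 genes at an estimated correlation gave p = 0.0217 in limma's camera, and an adjusted p = 0.0507 over the 7 lists made after the first look other than the 9 genes. Expression of these genes by tumour macrophages was not tested, and no gate against cavity cells was given.

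Cdh1 passed in MHCII-high at log2 1.73, and Epcam (1.84, adjusted p = 0.0702) did not. With the label number as a block both passed in limma (adjusted p = 0.0129 for Cdh1 and 0.0362 for Epcam). Tumour epithelial cells inside the MHCII-high gate could bring both, but keratins Krt7, Krt8, Krt18 and Krt19 left this open: their per-array mean differed by -0.15, with an upper 95% limit of 1.46, above the level that would exclude it. No explanation other than epithelial cells in the gate was tested for this pair.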

How the results depend on the processing

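The fit without either array numbered 20442 was chosen after seeing the data, and all other settings beforehand. Counts of genes past the threshold (1382; 751 higher in MHCII-high, 631 in MHCII-low; 989 at least 2-fold) stayed within 1.5 times under quantile normalization, normexp correction, both filters, the mean over probes and the series table. With the slide row as a block they were 455, 300, 155 and 449, and without both arrays numbered 20442 they were 374, 213, 161 and 354; fewer residual degrees of freedom are part of either construction. With 1 array left out the ranges were 555 to 1169, 308 to 663, 247 to 518 and 536 to 989, with 14 to 17 lists and an MHC class II shift of 1.14 to 1.34. With the label number as a block the counts were 809, 479 and 330, with 687 genes shared. Arrays of the same number had correlated deviations from their group means of 0.19, 0.13, 0.21 and 0.083, so only 3 of 4 passed 0.1 and the numbers were not taken to pair samples. All 8 arrays correlated best with their own number (highest between different numbers 0.076), a hint of pairs from the data and not the design. Pairing was therefore not excluded, and the counts with the label number as a block are those that would hold with pairs. Camera called 15 lists, and 0 with an estimated correlation (5 at an unadjusted p under 0.05; fry called 16).

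Over 17 alternatives, the calls of 85 named genes gave 1421 comparisons, of which 1128 kept the call, 293 lost it and 0 changed sign; 64 kept it with the label number as a block and 41 with the slide row as a block. Values of opposite sign to the reported one occurred in results that had not passed. The alternative activation list was at -0.018 with normexp, -0.065 with the mean over probes and -0.082 with the slide row as a block. With the mean over probes the T and NK cell list was at 0.00095 and Ndufs3 at 0.29. Without both arrays numbered 20442, immediate early genes were at 0.043, mitochondrial genes at 0.038 and Ndufs3 at 0.0039. Leaving out 1 array gave ranges of -0.071 to 0.12 for alternative activation, -0.076 to 0.039 for immediate early, -0.11 to 0.011 for mitochondrial, -0.16 to 0.54 for tumour epithelium, -0.015 to 0.13 for Ifi30 and -0.0069 to 0.10 for Rfxap. The cause was not tested. The fibroblast and pericyte list was the only list of the 15 to lose its call outside the estimated correlation, in 9 settings and with fry (adjusted p = 0.306), with a median of -0.21 without MHCII-high 20435. Dim signals limit log2 changes of genes below background in a group, and the offset of 50 in normexp makes them smaller by construction.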

Other observations

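The subset lists in this part were chosen only after dendritic cell genes had been seen to differ. Genes of type 1 conventional dendritic cells, which cross-present antigen, were higher in MHCII-high for 4 of 5: Itgae (log2 4.09), Clec9a (3.86), Batf3 (1.75) and Wdfy4 (1.24), while Xcr1 did not pass (adjusted p = 0.22). The median was 2.71 (2.62 in the highest other split of the arrays). Mature dendritic cell genes were higher for 4 of 4, Ccr7 (3.53), Ccl22 (at least 2.50-fold in the processed signal), Ccl17 (2.93) and Fscn1 (1.47), with a median of 3.13 (2.20 with Ccl22 at its bound). For type 2 conventional dendritic cells 3 of 4 were higher, Cd209a (3.06), Irf4 (2.44) and Mgl2 (0.98), while Clec4a4 was at -0.66 and did not pass, with a median of 1.71. As these genes were picked within a list seen to rise, no p-value is given for the subsets. Of 5 plasmacytoid genes limma called 0 (2 at an unadjusted p under 0.05), with a median of 0.051 and Ccr9 at 1.98 (adjusted p = 0.0538). With the slide row as a block the medians were 3.18, 3.17, 1.96 and 0.042.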
